A study of Mus musculus with 45 samples.

How the data were processed

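RNA was measured in 12 bulk libraries of mouse bladder urothelial organoids, in 6 groups of 2, and in 7 single-cell libraries of sorted bladder cells, 1 per mouse. Chromatin libraries of the same series were not analysed here. Per the labels' protocols, organoids grew in medium with EGF and an inhibitor of TGF-beta receptors among other additions, and bulk libraries were made from polyA RNA. Sorted cells were negative for DAPI and positive for EpCAM and nuclear EGFP, and were run on the 10x 3' version 3 chemistry with 1 mouse per library.

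The deposited bulk table holds unnormalized read counts of 53465 gene identifiers, per the file headers. Reads were aligned to mm10 with STAR 2.3, with Bowtie2 and Trim Galore named for other steps, per the submitters' processing notes; how reads were assigned to genes is not given in the sources used here. The deposited single-cell matrices hold UMI counts made with Cell Ranger, per the file headers, with EGFP and CreERT2 sequences added to mm10 and empty droplets not removed. Of the bulk identifiers 53274 (99.64%) matched a gene name. Coordinates came from the RefSeq annotation of GRCm38.p6, the mm10 build, and 97.31% of the named genes had them.

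Cells were barcodes above a UMI minimum, set in each library at 10% of the 99th percentile of its 3000 largest barcodes, with at least 500 genes and at most 20% mitochondrial UMIs. Doublets were called with the Scrublet method in scanpy, which marked 10 cells in all, far fewer than a rate of 0.8% per 1000 cells would give, so doublet removal did little here. Counts were normalized and log transformed in scanpy 1.11.5 (anndata 0.12.19), 2000 variable genes gave 30 principal components and 20 neighbours, and clusters were found with leidenalg 0.10.2 and igraph 0.11.9 at resolution 0.5, seed 1. Other tools were Python 3.11.15, scikit-learn 1.9.0, scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3. Clusters with a median mitochondrial share above 10% were left unnamed, and immune-like and fibroblast-like clusters were left out of urothelial cells. UMIs were summed per mouse over all urothelial cells and over each class, with at least 20 cells per mouse and class.

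The marker genes of the classes were fixed before the data were examined, but the rule that turns their score into a class was not. The first rule run puts a cluster in the basal-like class when its luminal minus basal score lies under the cell-weighted mean of its genotype, and it is the one used throughout. After its shares and scores were seen, a margin of 1 under the mean and a threshold of 0 for both genotypes were tried, and the margin served as the main rule for a time. The first rule was restored because no marker check required the margin, which changed whether a share difference was called with the cells used throughout; the report gives both.

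Counts were tested with edgeR 4.0.16 in R 4.3.3 by quasi-likelihood, with TMM normalization, its filter for low counts and Benjamini-Hochberg adjustment at 0.05. All 12 bulk libraries were fitted together in 6 groups, and mice as 4 control against 3 knockout. DESeq2 1.42.0 was the second tool. Gene lists, 37 in all and fixed before the data were examined, were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry. Shares were compared over the 35 splits of the 7 mice by exact permutation, two-sided. Recovery was tested on simulated data: at 2-fold edgeR recovered 10.2% of changed genes in the Cre comparison, 16.2% in the double-guide comparison and 76.6% in all urothelial cells, with 4, 2 and 9 unchanged genes called. DESeq2 recovered 41.7%, 42.9% and 77.8%, but called 40, 43 and 38 unchanged genes. Its bulk counts below may therefore hold many false calls.

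Named genes are the targets, then the 8 largest rises and 8 largest falls among genes past the threshold with an average log2 CPM of at least 3 and groups that do not overlap, without predicted, RIKEN and mitochondrial genes, then up to 4 members past the threshold of each list that passed camera or had at least 3 members past it. Members not past it are given as values, and some genes named by the rule are left out for length. Folds against groups without a UMI use a floor of 3 UMIs. The comparisons, the main tools and the first set of other settings were written before the data were examined. The mean double-loss effect of both bulk systems, the test of the difference between classes and its alternatives, the tests of knockout cells in control clusters, of the range of control clusters, of background RNA in other cell types and of UMIs per cell, a fixed minimum of 1000 UMIs, the removal of the highest doublet scores and the bounds of every test in the closing section were added after results were seen. Alternatives tried were RLE normalization, no low-count filter, a replicate block, each system alone, DESeq2, stricter cell filters, resolution 1.0, projection of knockout cells on control clusters, clustering without the changed genes, thinning the summed UMIs to the smallest total, and leaving out each library or mouse.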

Results

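RNA was measured in mouse bladder urothelial cells in which the histone methyltransferase genes Kmt2c and Kmt2d had been disrupted, singly or together, in 12 bulk libraries and 7 single-cell libraries. The bulk libraries came from cultured urothelial organoids in 6 groups of 2. In the CRISPR system, cells carried a lentiviral Cas9 vector with a control guide (sgControl), a Kmt2c guide (sgKmt2c), a Kmt2d guide (sgKmt2d) or both guides. In the Cre system, cells with both genes flanked by loxP sites received an adenovirus expressing mCherry alone (Cre control) or mCherry with Cre recombinase (Cre double knockout). The single-cell libraries came from sorted bladder cells of 4 untreated control mice and 3 double knockout mice, taken 3 months after 2 doses of 3 mg tamoxifen, which activates the CreERT2 recombinase. Every knockout mouse had received tamoxifen and no control mouse had, so the drug and the gene loss were given together. Nothing in the labels says whether bulk replicates came from separate cultures, so bulk p-values measure the spread between these libraries, which may be technical.

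Total bulk counts were 34353000 and 33853900 in sgControl, 32424400 and 34093200 in sgKmt2c, 38699700 and 41796300 in sgKmt2d, and 38414500 and 37559600 in the double-guide group. Those of the Cre system were 29364800 and 31007500 in control and 30420200 and 30828800 in knockout. Control mice 1 to 4 gave 4560, 4448, 5496 and 4020 cells, whose urothelial cells held 75721000, 59705300, 59594300 and 70314600 unique molecular identifiers (UMIs). Knockout mice 1 to 3 gave 2946, 3783 and 2905 cells, with 65786000, 68789200 and 63897200 UMIs in their urothelial cells. Median UMIs per cell ranged from 10146.5 to 16077 in control mice and from 16223 to 20403 in knockout mice. Levels below are CPM, counts scaled by library totals with TMM factors, as mean ± SD over libraries or mice (by plain totals for single clusters, cells of other types and knockout cells in control clusters), and changes are log2 fold changes ± SE.

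Kmt2c (ENSMUSG00000038056, chromosome 5, 25271795 to 25498855 in mm10) fell in the knockout mice, from 78.7 ± 4.62 CPM (n = 4) to 38.0 ± 3.27 CPM (n = 3), a log2 change of -1.05 ± 0.08 (edgeR adjusted p = 7.07e-06). Kmt2d (ENSMUSG00000048154, chromosome 15, 98831669 to 98874077) fell less, from 28.3 to 21.4 CPM, a log2 change of -0.41 (edgeR adjusted p = 9.51e-04). Kdm6a (ENSMUSG00000037369, chromosome X, 18160862 to 18279936), which encodes a demethylase that works with both enzymes, differed by a log2 value of 0.17 from 17.8 CPM in control mice (edgeR adjusted p = 0.0696). In Cre organoids Kmt2c was at 48.7 ± 7.47 CPM in control and 29.2 ± 2.88 CPM in knockout (n = 2 each, log2 -0.74, edgeR adjusted p = 0.256), while Kmt2d was at 60.4 and 65.8 CPM. In the CRISPR system Kmt2c was at 64.8 ± 1.35 CPM in sgControl, 43.7 ± 14.0 in sgKmt2c, 74.8 in sgKmt2d and 59.9 ± 6.14 with both guides. Kmt2d was at 90.5 ± 8.10 CPM in sgControl, 85.2 ± 1.87 in sgKmt2d and 103 ± 4.32 with both guides, and no CRISPR change of either gene passed the threshold. Small guide-made deletions need not lower the transcript, and 3' tags or reads outside the deleted exons check nothing, so these levels do not test whether the proteins were lost.

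**Figure D1:**
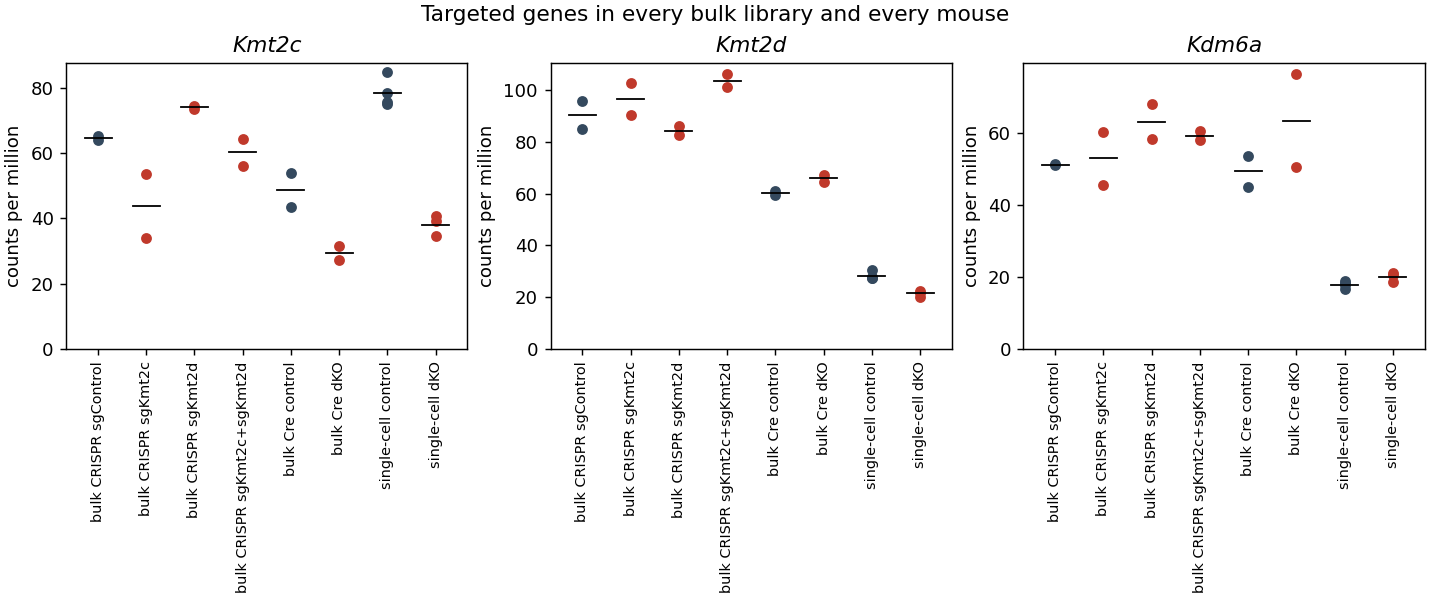
Kmt2c, Kmt2d and Kdm6a in CPM (vertical axes, from 0) in each bulk library and each mouse, one point per library or mouse, by group. Kmt2c averaged 38.0 CPM in the 3 knockout mice against 78.7 CPM in the 4 control mice, while Kmt2d with both guides, at 103 CPM, lay no lower than sgControl at 90.5 CPM.

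The first comparison asked what the double knockout changed in sorted urothelial cells of the bladder. The uroplakin genes Upk3a and Upk3b, which encode plaque proteins of the luminal surface, fell: Upk3a went from 1884 ± 244 CPM in control mice to 159 ± 47.2 CPM in knockout mice (log2 -3.57 ± 0.22), and Upk3b from 99.6 to 3.79 CPM (-4.72). Krt20, a keratin of superficial cells, fell to 0.397 CPM (-6.19), and the cornified envelope gene Ivl from 1284 to 121 CPM (-3.41). Krt14, a keratin of basal cells, rose from 6.41 ± 2.46 to 188 ± 175 CPM (4.87 ± 0.62, edgeR adjusted p = 1.63e-04). In all, 7772 of 13821 genes passed an edgeR adjusted p of 0.05, 3948 higher and 3824 lower, and 1273 of them differed at least 4-fold, 686 higher and 587 lower. DESeq2 gave 8007 genes, and mice of the 2 groups did not overlap for 8145 of the 13821 genes, 58.9%, against a chance share of 5.71%.

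Among well expressed genes, the largest rise was in Grp, the gastrin-releasing peptide gene (chromosome 18, 65872751 to 65886599). It had 0 UMIs in control mice and 5577 in knockout mice, 25.6 ± 25.5 CPM, at least 2260-fold higher than a floor of 3 UMIs over the group. Tmprss11g (chromosome 5, 86485877 to 86518600), a membrane serine protease gene, rose from 1.41 to 74.0 CPM (5.68), and the chemokine gene Cxcl15 (chromosome 5, 90794534 to 90803067) from 2.94 to 44.0 CPM (3.89). Sdk1, Nccrp1 and Fst, the follistatin gene, rose by log2 values of 4.16, 3.77 and 3.69. The histone gene Hist1h1b (chromosome 13, 21779832 to 21780625) rose from 0.366 to 28.3 CPM (6.25). Cyp4f15 (chromosome 17, 32685631 to 32703352), a cytochrome P450 gene, fell from 41.2 ± 7.25 to 0.139 ± 0.168 CPM, and Fgf1 (chromosome 18, 38838672 to 38929470) from 16.2 to 0.0584 CPM (-8.10). Galnt16 and Hsd17b14 fell by 8.08 and 6.55 on the log2 scale. Sept4 fell from 31.2 to 0.402 CPM (-6.28) and the imprinted gene Peg3 (chromosome 7, 6703892 to 6730462) by 5.95. Krt14 and Grp were carried unevenly by the mice, since knockout mouse 2 held 676 of the 920 cells of the cluster in which both genes were high. Pgr and Ccn2 (Ctgf), given below, were also among the leading genes of that cluster by fold over other clusters.

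Genes of lipid metabolism fell together. Of 20 measured genes of the PPAR and fatty acid list, 0 rose and 19 fell, among them the lipid droplet gene Plin2, from 329 ± 67.0 to 64.3 ± 9.15 CPM (-2.36), and the fatty acid binding protein gene Fabp5, from 400 to 81.6 CPM (-2.29). Of 20 cholesterol synthesis genes, 17 fell, with Sqle at -1.88 and Lss at -1.86, and 1 rose. Luminal differentiation genes fell in 13 and rose in 4 of 22 cases, and the tight junction gene Cldn3 was among those that rose, from 0.0448 to 1.76 CPM. Of 24 genes of EGFR ligands and MAPK feedback, 15 fell and 4 rose, with Tgfa going from 27.9 to 7.44 CPM (-1.91) and Dusp4 from 83.7 to 23.6 CPM (-1.82). These lists passed camera, which compares a list with all other genes at a preset correlation, at adjusted p = 2.91e-11 (fatty acid), 1.23e-07 (cholesterol), 2.61e-04 (luminal) and 0.0350 (EGFR). With an estimated correlation the adjusted p rose to 0.250, 0.430, 0.509 and 0.332.

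Genes of the interferon response rose in 20 and fell in 3 of 24 cases, with the antiviral genes Ifi44, Rsad2 and Rtp4 up by 6.00, 5.42 and 5.21, each from under 0.1 CPM in control mice. Inflammatory genes rose in 14 and fell in 1 of 18 cases. Cxcl1, a neutrophil chemokine gene, rose from 7.16 to 34.7 CPM (2.28), and Tslp by 3.17, while the alarmin gene Il33 fell from 71.2 to 14.2 CPM. Class I antigen presentation genes rose in 9 and fell in 1 of 13 cases, with B2m at 193 ± 8.09 and 376 ± 11.6 CPM (0.96), H2-Q4 up by 1.63 and H2-T23 down (-1.47). Class II genes rose in 5 and fell in 1 of 6 cases, such as H2-DMb1 from 2.47 to 10.1 CPM (2.03). Camera adjusted p was 3.37e-07 (interferon), 1.85e-05 (inflammatory), 0.00142 (class I) and 0.0321 (class II), and 0.477, 0.319, 0.509 and 0.549 with an estimated correlation. Immune cell markers moved the same way at very low levels: Lyz2 rose from 0.319 to 1.12 CPM and Fcer1g from 0.0779 to 0.215 CPM, 3 of 3 measured markers higher (camera adjusted p = 0.277).

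Hox genes rose in 14 and fell in 3 of 25 cases, with Hoxb13 going from 2.35 to 5.88 CPM (1.32) and Hoxb3 from 5.79 to 13.1 CPM (1.18). Other developmental transcription factors rose in 12 and fell in 1 of 18 cases, led by Isl1 (5.39), Sox2, from 3.31 to 10.6 CPM (1.67), and Meis2, from 16.1 to 44.5 CPM (1.47). Cell cycle genes rose in 19 and fell in 0 of 31 cases, such as E2f1 (4.09) and Aurkb (2.47). Camera adjusted p was 0.0412, 0.0321 and 0.0202, and 0.549, 0.549 and 0.827 with an estimated correlation. All urothelial cells include a cluster of proliferating-like cells, which held 134 knockout and 18 control cells. The rise of cell cycle genes was therefore not told from a larger share of such cells. Immediate early genes rose in 22 and fell in 6 of 40 cases, with Egr3 at 18.3 and 109 CPM (2.58), Arc at 13.8 and 89.6 CPM (2.70) and Gadd45b at 112 and 536 CPM (2.26), while the list missed the threshold (camera adjusted p = 0.0523). Heat shock genes, which respond to tissue dissociation, rose in 7 and fell in 1 of 12 cases, with Hspa1a at 129 ± 57.6 and 346 ± 64.0 CPM (1.42, camera adjusted p = 0.237 for the list). Smooth muscle genes rose in 3 of 4 cases at low levels, Acta2 from 0.159 to 1.64 CPM (camera adjusted p = 0.132).

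Several lists held genes that moved apart. Basal genes rose in 10 and fell in 8 of 20 cases, with Krt5 going from 1195 ± 51.3 to 2323 ± 136 CPM (0.96), and Krt17 up by 3.53, while Ngfr fell from 0.482 to 0.0513 CPM (-3.16). Squamous genes rose in 7 and fell in 5 of 15 cases (median 0.35, although camera ranked the list lower, adjusted p = 0.956), with Krt16 up by 5.10 and Sprr1a down from 4504 to 376 CPM (-3.58). Targets of the estrogen receptor, listed because tamoxifen acts on it, rose in 3 and fell in 3 of 7 cases (camera adjusted p = 0.683). The receptor gene Esr1 rose from 7.05 to 18.8 CPM (1.41) and Greb1 by 6.09, while Tff1 fell by 2.76. Pgr had 2 UMIs in all control mice, 0.00864 CPM, and stood at 5.04 ± 5.62 CPM in knockout mice. Adjusted over the list alone, the counts of the lists above were the same, except for luminal genes (14 lower), cell cycle genes (21 higher) and immediate early genes (23 higher).

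Other lists of the same cells did not pass camera. Unfolded protein response genes rose in 6 and fell in 1 of 15 cases (adjusted p = 0.205), and Wnt targets rose in 6 and fell in 3 of 9 (0.171), with Axin2 up by 3.77. Ribosomal protein genes fell in 5 of 20 cases (0.265), and genes of oxidative phosphorylation rose in 2 and fell in 5 of 18 (0.675). Those of the mitochondrial genome, a gauge of RNA quality, rose in 2 and fell in 5 of 13 (0.688). Glutathione and NRF2 genes rose in 3 and fell in 6 of 16 (0.244), glycolysis and hypoxia genes rose in 6 and fell in 6 of 18 (0.902), and Notch genes rose in 3 and fell in 5 of 10 (0.758). Polycomb genes rose in 5 and fell in 4 of 15 (0.601, median -0.07 and mean 0.16), genes of KMT2 complexes rose in 3 and fell in 4 of 18 (0.992), and p53 targets rose in 8 and fell in 7 of 19 (0.759). Retinoid genes rose in 4 and fell in 3 of 9 (0.962, median 0.52 although camera ranked them lower), with Cyp26b1 up by 4.58 and Rdh10 down by 2.39. Hedgehog and BMP genes rose in 6 and fell in 4 of 10 (0.647, median 0.37 and mean -0.13), Bmp2 and Bmp7 falling by 2.05 and 2.16. Mesenchymal genes rose in 8 and fell in 4 of 12 (0.940), with Sparc down from 11.7 to 0.225 CPM (-5.69), endothelial genes rose in 1 of 2 (0.647), and 0 of 3 neuroendocrine genes passed (0.956). Adjusted over the list alone, 7 glutathione and 8 glycolysis genes were lower and 3 genes of KMT2 complexes were.

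**Figure D2:**
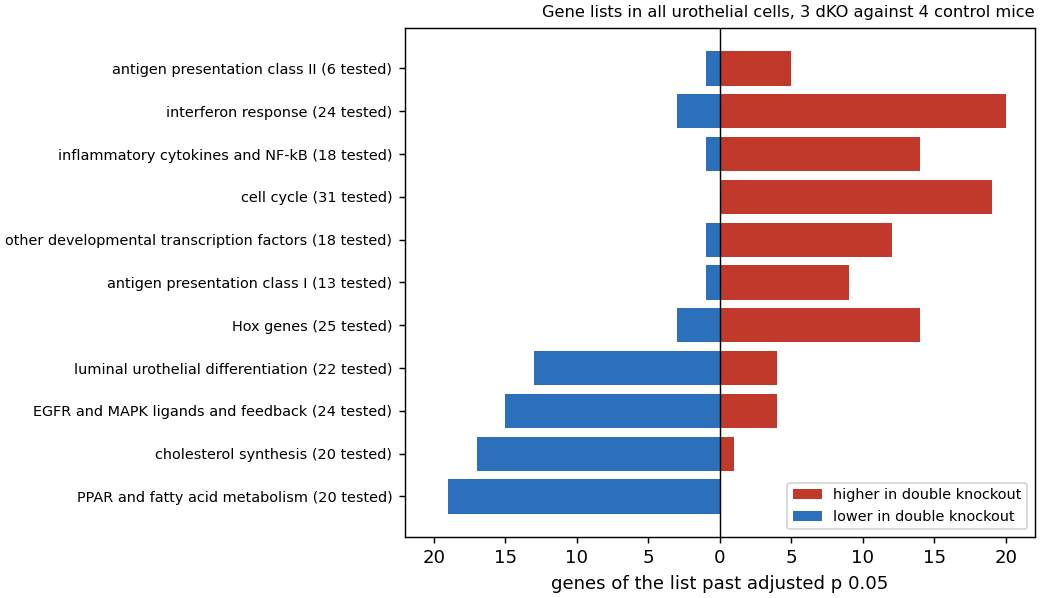
Number of genes past an edgeR adjusted p of 0.05 (horizontal axis) in each gene list that passed camera at the preset correlation, higher to the right and lower to the left of 0, in all urothelial cells of 3 knockout against 4 control mice. Of 20 fatty acid genes 19 were lower and of 24 interferon genes 20 were higher.

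The next question was whether both layers of the urothelium changed alike. Clusters scoring high for basal or luminal marker genes relative to the mean of their own genotype were called basal-like and luminal-like. Control and knockout cells formed separate clusters, so different clusters filled each class: clusters 2 and 5 (control) and 3 and 6 (knockout) for basal-like, 0 and 4 (control) and 1 and 9 (knockout) for luminal-like. The classes are therefore relative ones: control cluster 2, basal-like, scored 0.92 and knockout cluster 1, luminal-like, 0.959 on the same scale of luminal minus basal marker expression.

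In basal-like cells 6062 of 12410 genes passed (3005 higher, 3057 lower; DESeq2 6104). Uroplakin RNA was lower in knockout basal-like cells: Upk3a went from 688 ± 146 to 8.14 ± 6.47 CPM (log2 -6.42 ± 0.59), Upk1a from 878 to 10.8 CPM (-6.34) and Upk3b from 55.1 to 0.239 CPM (-7.90). Of the control clusters in this class, cluster 5 held Upk3a at 1512 CPM and cluster 2 at 230 CPM. A Upk3a UMI was found in 66.7% of control basal-like cells (median 11288 UMIs) and in 53.7% of 41 control immune-like cells (median 7641 UMIs, Upk3a at 556 CPM), so free RNA of other cells was not told from expression here. Caveolin gene Cav1 rose from 0.537 ± 0.0867 to 43.5 ± 10.3 CPM (6.36), Hist1h1b by 8.06, Prss23 by 5.80, Gcnt2 by 5.71 and Pcdhb9 by 5.02. Krt14 rose to 442 ± 343 CPM (4.48), and Grp, with 0 UMIs in control mice, stood at 62.3 ± 52.9 CPM, at least 1730-fold above the floor of 3 UMIs. Peg3 fell from 244 to 2.85 CPM (-6.42), while Hsd17b14 (-7.29), Wfdc15b (-7.08), Cyp4f15 (-6.95) and Cmbl (-6.58) fell too. The matricellular gene Ccn2 had 1 UMI in control mice, 0.0130 CPM, and stood at 23.8 ± 28.4 CPM, Iqgap2 had 3 UMIs, 0.0419 CPM, and stood at 21.3 CPM, and Fgf1 went from 23.6 CPM to 2 UMIs in all knockout mice. Kdm6a rose in these cells, from 20.2 to 25.8 CPM (0.36, edgeR adjusted p = 0.00852).

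By list, basal-like cells showed the fall of fatty acid genes (18 of 20), with Plin2 going from 335 to 28.7 CPM (-3.55) and Fabp4 by 4.34 lower, of cholesterol genes (16 of 20, 2 higher) and of luminal genes (13 of 21, 1 higher). Glutathione and NRF2 genes fell in 10 and rose in 1 of 16 cases, such as Gsta2 (-4.24) and Gstm1, from 10890 to 2234 CPM (-2.29). Of 20 ribosomal protein genes, 14 fell and 0 rose (17 fell, adjusted over the list alone), such as Rpl5, from 3462 to 1888 CPM (-0.87). Immediate early genes rose in 20 and fell in 5 of 39 cases (22 higher, adjusted over the list alone), Egr3 from 43.0 to 209 CPM. Class I genes rose in 10 of 13 cases, B2m from 140 to 434 CPM (1.63), class II genes in 5 of 6, inflammatory genes in 12 of 15, interferon genes in 9 of 16, developmental transcription factors in 11 of 16 and smooth muscle genes, at low levels, in 3 of 3. Camera adjusted p lay between 3.78e-11 (fatty acid) and 0.0398 (interferon and smooth muscle) for these lists, and none of them passed with an estimated correlation, where the smallest adjusted p was 0.197. The luminal count was 14 lower when adjusted over the list alone, and counts not given in this way were the same.

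In luminal-like cells 7414 of 13120 genes passed (3724 higher, 3690 lower; DESeq2 7405). Upk3a fell from 2361 ± 210 to 248 ± 41.7 CPM (log2 -3.25 ± 0.14), Upk3b from 117 to 5.90 CPM (-4.30) and Krt20 from 35.2 to 0.559 CPM (-5.96). The claudin gene Cldn8 fell from 23.4 to 0.372 CPM (-5.97), the arginase gene Arg2 by 7.72, Cyp4f15 from 50.5 to 0.136 CPM (-8.48), and Hsd17b14 fell too (-6.20). Tmprss11g rose from 1.41 to 95.8 CPM (6.06), the decoy receptor gene Il1r2 by 5.05 from 1.60 CPM, Serpine2 by 6.49, Scin by 5.13, Nccrp1 by 4.25 and Cxcl15 by 3.95. The basal keratin gene Krt14 was at 0.528 and 18.8 CPM (5.12), with a UMI in 4.94% of knockout luminal-like cells (median 23239 UMIs) against 12.9% of 62 knockout immune-like cells (median 17171.5 UMIs), so it is read as background. The hemidesmosome gene Col17a1 was at 23.8 and 114 CPM (2.26), with a UMI in 77.0% and 56.5% of the same cells. By plain totals it was at 119.9 CPM in knockout luminal-like cells and 98.35 CPM in knockout immune-like cells. In knockout droplets under the smallest number of UMIs kept it was at 118.2 CPM, so its level was not told from background either. The laminin gene Lama3 fell (-3.63). Interferon genes rose in 20 and fell in 1 of 23 cases, such as Oasl2 (5.30), inflammatory genes rose in 13 of 17, class I genes in 10 of 13, Hox genes in 13 of 24 and developmental factors in 9 of 14. Fatty acid genes fell in 17 of 20 cases, with Elovl6 at -2.26, cholesterol genes in 17 of 20, luminal genes in 12 of 22 and EGFR and MAPK genes in 15 of 24. Camera adjusted p lay between 1.03e-09 and 0.0377 for these lists, and none passed with an estimated correlation (smallest adjusted p = 0.284). Adjusted over the list alone, 16 EGFR and MAPK genes, 2 class I genes and 2 developmental factors were lower, and other counts were the same.

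Across genes the 2 classes gave like changes: 2189 genes rose in both and 2366 fell in both, against 836 and 860.5 expected of independent lists, while 84 went opposite ways. The log2 changes correlated at r = 0.878 over 12297 genes, which are not independent replicates. Both classes come from the same mice. On summed log CPM over 10704 genes r was 0.850, and 3 splits of the control mice, with no effect, gave a mean r of 0.632 (0.520 to 0.714). The covariance was 0.640, against 0.0177 for those splits.

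A test of the difference between the classes, added after the data were seen, gave 3858 of 13384 genes, 1698 with the higher change in basal-like cells and 2160 with the lower. Ribosomal protein genes all lay on one side, with the lower change in basal-like cells for 20 of 20 (camera adjusted p = 8.01e-07). Glutathione and NRF2 genes changed lower there in 12 of 16 cases (5.67e-18) and squamous genes in 9 of 14 (4.56e-05). Luminal genes did so in 14 of 22 (3.81e-11), but the 10 luminal markers that formed the classes, Upk1a and Upk3a among them, are members of this list, so its difference in part restates the class rule. Immediate early genes had the higher change in 19 and the lower in 10 of 39 cases (0.0108). With an estimated correlation the camera adjusted p of these lists was 0.576, 0.0781, 0.0803, 0.208 and 0.272. The change in Upk1a was lower by 4.20 in basal-like cells, that in Ivl by 2.14 and that in Gstm1 by 2.07. The size of these differences, and for some genes the sign, depended on how the classes were formed. With knockout cells placed on control clusters, Upk1a differed by -0.87, Gstm1 by -0.61 and Upk3a by -0.06 (edgeR adjusted p = 0.643). With the clusters above, Upk3a differed by -3.30. Klf2 differed by -2.42 with these clusters and by 0.821 with the margin of 1 (edgeR adjusted p = 1.09e-09 and 2.63e-05). Krt14 differed by -0.659 with these clusters and by 1.36 under projection (edgeR adjusted p = 0.00161 and 2.96e-04). The ribosomal, glutathione, squamous, luminal and immediate early lists kept their direction and passed camera under the 3 other ways of forming the classes. So did class I genes, with the higher change in basal-like cells in 5 and the lower in 2 of 13 cases (camera adjusted p = 0.0102, 0.576 with an estimated correlation). Inflammatory genes changed lower there in 9 of 18 cases (camera adjusted p = 0.00153) and Notch genes in 5, and higher in 2, of 9 (0.0256), both with an adjusted p of 0.293 with an estimated correlation, but the first missed the threshold with the margin of 1 (0.166) and at resolution 1.0 (0.0663) and the second with the margin (0.139) and under projection (0.813). Genes of the mitochondrial genome, a gauge of RNA quality, changed lower there in 8 and higher in 0 of 13 cases (camera adjusted p = 0.173). Those of oxidative phosphorylation did so in 8 and 0 of 18 (0.0905). The mitochondrial list passed camera only under projection (0.0445), and the oxidative phosphorylation list under the 3 other ways of forming the classes. So did Hedgehog and BMP genes, with the higher change in basal-like cells, after missing at first (camera adjusted p = 0.0805). Hox genes changed higher there in 1 and lower in 5 cases at first (camera adjusted p = 0.606). That turned to 9 and 1 with the margin and 8 and 1 under projection (camera adjusted p = 0.00528 and 0.00955). Further lists passed under some of these ways only.

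No difference in the share of basal-like cells was called with the first rule and the cells used throughout. They made up 35.6 ± 6.84% of urothelial cells in control mice (n = 4, range 26.1 to 42.4%) and 45.9 ± 7.45% in knockout mice (n = 3, range 38.9 to 53.7%; exact permutation p = 0.114, two-sided, smallest possible 0.0286). Luminal-like cells made up 62.9 ± 6.57% and 52.8 ± 8.29% (exact permutation p = 0.171, n = 4 and 3). The genes that define these clusters differed between genotypes. Clustered without the genes that passed the test, the basal-like share was 59.9% in control and 51.9% in knockout mice (exact permutation p = 0.257), the opposite direction. At resolution 1.0 it was 44.5% and 45.9% (exact permutation p = 0.857). Cluster 5 held 11.4 ± 6.12% of control and 0.258% of knockout cells (exact permutation p = 0.0571), and its Upk3a level, 1512 CPM, was nearer to the 1606 CPM of luminal-like cluster 0 than to the 230 CPM of basal-like cluster 2. With a margin of 1 in the marker score, set after these values were seen, cluster 5 joined the luminal-like class and the basal-like share was 24.2% against 45.6% (exact permutation p = 0.0286). The UMI minimum for a cell ran from 2600.9 to 4484.8 in control and from 4940.5 to 5533.4 in knockout libraries. With an added minimum of 1000 UMIs in every library and the first rule, the basal-like share was 23.5% against 51.1% (exact permutation p = 0.0286). Cells were clustered anew for this, which moved more cells than the minimum added. In control mouse 1 urothelial cells went from 4543 to 4601, but basal-like cells from 1928 to 1004. Clustering anew with called doublets kept moved basal-like cells to 1106 there, and from 2057 to 2707 in control mouse 3. Class membership thus changed with each clustering. Proliferating-like cells made up 1.33 ± 0.893% in knockout and 0.0988 ± 0.0793% in control mice (exact permutation p = 0.0286, n = 3 and 4), and 1.14% against 0.110% without the changed genes (exact permutation p = 0.0286). With knockout cells placed on control clusters they made up 0.493% against 0.110%, and the call was lost (exact permutation p = 0.0571). The sort for EpCAM and nuclear EGFP sets which cells could be counted. The EGFP transcript itself was at 79.6 CPM in control mice (65.6 to 101.5) and 38.9 CPM in knockout mice (35.4 to 41.1). The gate may therefore have let through different cells in the 2 groups, which was not tested. Of all cells kept, immune-like cells made up 0.234% in control and 0.608% in knockout mice (exact permutation p = 0.114), and fibroblast-like cells 0.117% and 0.0492% (exact permutation p = 0.0286). The fibroblast-like share rests on few cells, 5, 5, 8 and 4 in control mice and 1, 3 and 1 in knockout mice.

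**Figure D3:**
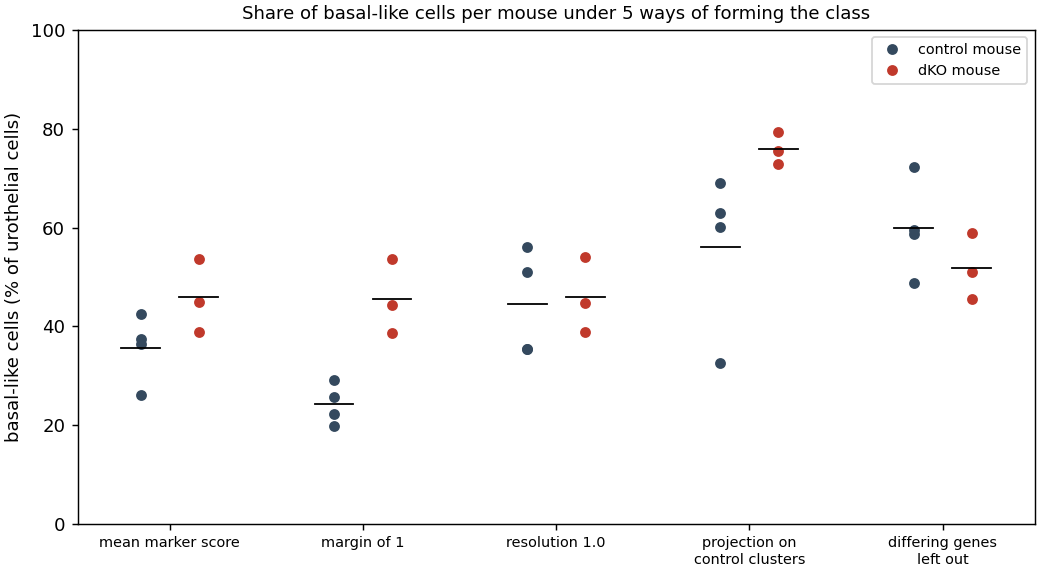
Share of basal-like cells in percent of urothelial cells (vertical axis) per mouse, with 4 control and 3 knockout points and their mean for each of 5 ways of forming the class. The first way gave means of 35.6% and 45.9%, the margin of 1 gave 24.2% and 45.6%, and leaving out the changed genes turned the order to 59.9% and 51.9%.

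The Cre organoids asked what the same double knockout did in culture, with 2 libraries against 2. Mkx (chromosome 18, 6934966 to 7004779), a homeobox transcription factor gene, rose from 0.239 ± 0.00994 to 8.90 ± 0.259 CPM (log2 5.20 ± 0.46, edgeR adjusted p = 0.0316). It was the single gene of 15087 past the threshold, and the call was lost without any 1 of the 4 Cre libraries and with these libraries alone. By unadjusted p under 0.05 there were 1650 genes, and DESeq2 called 361 (230 higher, 131 lower). In simulated data of this comparison edgeR recovered 57.9% of 4-fold and 10.2% of 2-fold changes. Developmental transcription factors other than Hox genes had a median log2 change of 0.69 over 23 genes and Hox genes one of 0.43 over 25 (camera adjusted p = 5.48e-04 and 0.00173, both 0.0971 with an estimated correlation). Their members included Hoxb13, at 2.48 ± 0.546 and 15.4 ± 9.15 CPM, Hoxa13, at 5.63 and 19.9 CPM, and Tbx3, at 16.5 and 45.6 CPM. Interferon genes had a median of 0.38 over 25 genes, such as Oas1a, at 0.658 and 5.96 CPM, and Irf9, at 8.73 and 16.5 CPM, and class I genes a median of 0.34 over 12 (camera adjusted p = 0.00490 and 0.0290). Immediate early genes (median 0.19, 38 genes) and cell cycle genes (median -0.15, 31 genes) passed at adjusted p = 0.0290 and 0.0239, and these 4 lists had an adjusted p of 0.903 with an estimated correlation. Ngfr, the low-affinity nerve growth factor receptor gene of the basal list, was at 20.8 ± 4.67 and 0.790 ± 0.172 CPM (-4.71). No member of these lists passed over all genes; adjusted over the list alone, 1 interferon, 1 class I and 1 immediate early gene were higher and Ngfr was lower.

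Loss of one gene at a time was compared with sgControl in the CRISPR organoids. With the Kmt2c guide, genes of the unfolded protein response had a median log2 change of 0.47 over 15 genes: the chaperone gene Hspa5 was at 879 ± 86.4 CPM in sgControl and 1670 ± 44.3 CPM in sgKmt2c, Hsp90b1 at 995 and 1620 CPM and Calr at 866 and 1372 CPM. The list passed camera (adjusted p = 1.28e-10, 0.189 with an estimated correlation). Adjusted over the list alone 7 members were higher, against 0 over all genes. Interferon genes had a median of 0.43 (camera adjusted p = 0.00349, 0.762 with an estimated correlation), and camera ranked the list lower instead without sgKmt2c library 1 (adjusted p = 0.843). Krt4, a keratin of the squamous list, was at 1103 ± 354 and 206 ± 22.7 CPM (-2.42, edgeR adjusted p = 0.309). In this comparison edgeR called 0 genes, 602 had an unadjusted p under 0.05, and DESeq2 called 23.

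With the Kmt2d guide, against the same 2 sgControl libraries, so not as a separate repeat, the unfolded protein response list was higher (median 0.70, camera adjusted p = 2.67e-10, 0.197 with an estimated correlation; 9 members adjusted over the list alone, 0 over all genes). Hspa5 was at 1798 ± 121 CPM, Hsp90b1 at 1827 ± 239 and the transcription factor gene Xbp1 at 120 ± 7.14 against 64.2 ± 17.6 CPM in sgControl. Basal genes had a median of 0.66 over 20 genes and squamous genes one of 1.37 over 22 (camera adjusted p = 8.65e-04 for each), and inflammatory genes one of -0.53 over 21 (0.00630), all with an adjusted p of 0.899 with an estimated correlation. The desmosome gene Dsg3 was at 196 ± 45.0 and 561 ± 124 CPM, Krt6b at 1.76 ± 1.15 and 83.4 ± 85.1 CPM and Ngfr at 37.6 ± 14.1 and 0.616 ± 0.581 CPM. Adjusted over the list alone, 4 basal genes were higher and 1 lower, 1 squamous gene was higher, and 0 inflammatory genes passed. edgeR called 0 genes over all genes, 2250 had an unadjusted p under 0.05, and DESeq2 called 574 (259 higher, 315 lower).

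With both guides, against the same sgControl libraries, unfolded protein response genes had a median of 0.68 (camera adjusted p = 1.84e-10, 0.185 with an estimated correlation; 9 higher adjusted over the list alone), with Hspa5 at 1694 ± 219 and Xbp1 at 121 ± 1.08 CPM. Basal genes had a median of 0.77 and squamous genes one of 1.30 (camera adjusted p = 0.00119 for each), such as Dsg3, at 584 ± 47.7 CPM, the laminin gene Lamb3, at 450 ± 132 against 204 CPM, and Krt6b, at 116 ± 107 CPM. Ngfr was at 0.396 ± 0.279 CPM. Glutathione and NRF2 genes had a median of -0.38, with Gstm1 at 19.2 ± 2.69 in sgControl and 5.26 ± 0.405 CPM, immediate early genes one of 0.25 and cholesterol genes one of 0.14 (camera adjusted p = 0.0324, 0.0324 and 0.0485). Apart from the unfolded protein response, these lists had an adjusted p of 0.782 with an estimated correlation, and adjusted over the list alone 6 basal, 1 squamous and 1 immediate early gene were higher and 1 basal and 1 glutathione gene lower. edgeR called 0 genes, 2094 had an unadjusted p under 0.05, and DESeq2 called 616 (338 higher, 278 lower).

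Between the single guides, P3h4 (chromosome 11, 100408467 to 100414716), a gene of collagen hydroxylation, was higher with the Kmt2d guide, 58.0 ± 2.97 against 12.0 ± 3.01 CPM (2.28, edgeR adjusted p = 0.0198). Capn1 (chromosome 19, 5988545 to 6015825), a calpain gene, was lower, 112 ± 0.730 against 206 ± 5.53 CPM (-0.88, edgeR adjusted p = 0.0383). These were the 2 genes past the threshold, against 1931 by unadjusted p and 467 by DESeq2, and both calls were lost without either sgKmt2d library and with CRISPR libraries alone, that of Capn1 also without either sgKmt2c library. Squamous genes differed by a median of 1.12 and basal genes by 0.57 (camera adjusted p = 4.58e-05 and 0.00355, both 0.625 with an estimated correlation). Inflammatory genes (median -0.94), class I genes (-0.36) and glutathione and NRF2 genes (-0.37) had an adjusted p of 0.0287, estrogen receptor targets (0.31) one of 0.0452 and genes of the mitochondrial genome (0.21) one of 0.0477. Under other settings these 7 list calls were lost in 24 cases and kept in 32, and none of the 7 passed under all of them. With an estimated correlation the mitochondrial list had an adjusted p of 0.680 and the other 4 one of 0.625. Adjusted over the list alone, 2 squamous, 2 basal and 1 estrogen target gene were higher, and 1 basal and 1 glutathione gene lower. Krt4 was at 206 CPM with the Kmt2c guide and 1089 ± 151 CPM with the Kmt2d guide, and Gstm1 at 29.5 ± 12.0 and 7.11 ± 0.143 CPM. The test of whether the guides combined other than additively called 0 genes in edgeR, with 172 by unadjusted p and 2 by DESeq2. Of the lists, the unfolded protein response differed from additivity (median -0.43, camera adjusted p = 4.37e-08, 0.355 with an estimated correlation; 2 members lower adjusted over the list alone, 0 over all genes). For the difference of the double-loss effect between the Cre and CRISPR systems edgeR called 0 genes, 400 had an unadjusted p under 0.05 and DESeq2 called 7.

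Fold changes were then compared across systems, over genes that are not independent replicates. Cre double knockout and double-guide changes correlated at r = 0.538 (jackknife SE 0.0557 over libraries, 15087 genes), and 68.5% of genes had the same sign. Cre organoid and single-cell changes correlated at r = 0.368 (jackknife SE 0.0604, 12238 genes). In Cre organoids Upk3a was at 12.3 ± 12.6 and 23.6 ± 18.2 CPM and Plin2 differed by a log2 value of 0.11 (edgeR adjusted p = 0.959), while both fell in mice; mice and organoids were not tested against each other. The single guides share their sgControl libraries: their changes gave r = 0.401 in log CPM, against 0.504 in 20 simulations with no effect, and a covariance of 0.132 against 0.121.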

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

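All tests of explanations in this part were chosen only after the results were seen. The number of genes that changed in the knockout mice was far above that of any other split of the mice. In all urothelial cells 7772 genes passed edgeR, and 1 of 35 splits, the real one, gave as many, the highest other giving 1. In basal-like cells 1 of 35 splits reached 6062 (highest other 0), and in luminal-like cells 1 of 35 reached 7414 (highest other 0). Since 35 splits can give no share under 0.0286, chance in how the mice fell into groups is unlikely but not excluded. The class rule uses the mean score of each genotype, so within the classes the real split was favoured in advance. Cells of knockout mice held more UMIs. With the summed UMIs of every mouse thinned in proportion to the lowest median per cell, 10146.5 UMIs, 7303 genes passed. Of the 7772, 7105 passed again in the same direction. Thinning sums keeps the expected level of each gene, so it shows only that fewer UMIs would still give most calls. Whether depth per cell acted through the barcodes kept or the clusters was not tested. Tamoxifen or a preparation shared by the knockout mice may still account for part: estrogen receptor targets did not move as a list (camera adjusted p = 0.683), but no untreated knockout or treated control mice separate drug from gene loss.

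A shift between states that control mice also hold stays open for the large changes. Of the 1273 genes at least 4-fold apart, 82.95% had every knockout mouse outside the range of 5 control clusters, but 61.82% with the 18 proliferating control cells counted and 36.53% with control cells split into 60 clusters. Knockout mice also had 177 cells in control clusters, whose Kmt2c level was 42.1 CPM, near the 40.3 CPM of other knockout cells and under the 75.0 CPM of control cells. This excludes that all of them were control cells, while a smaller share of unrecombined cells could be present.

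The second sgKmt2d library and the second double-guide library were unusually alike, with a chi-square of 16.2 per degree of freedom, where 37.4 was the lowest within any group. Copies of 1 library would lie near 1, so they are separate libraries. The first libraries of these 2 groups lay at 37.7, under the 78.8 within sgKmt2d and the 110 within the double-guide group. The likeness was therefore not limited to the second libraries. Replicate differences of these 2 groups correlated at 0.753, which could come from a shared culture or day. The other pairs among guide groups correlated at 0.358 and 0.355 and those with sgControl at -0.103 to 0.0284, so the cause stays open.

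Some results went against a simple picture. With both guides the unfolded protein response list rose less than the sum of the single guides (camera adjusted p = 4.37e-08, 0.355 with an estimated correlation), which low levels in the sgControl libraries shared by all guide comparisons would also give. The double-loss effect differed between the Cre and CRISPR systems in 8 lists by camera. Their adjusted p was 0.0318 for luminal genes, 0.0105 for squamous genes, 0.00597 for inflammatory genes, 0.0105 for class I genes, 0.0105 for Hox genes, 0.0377 for developmental factors, 0.0318 for glutathione and NRF2 genes and 1.29e-11 for the unfolded protein response. Under other settings these calls were kept in 56 cases, lost in 31 and reversed in 1, and only the unfolded protein response passed under all. With an estimated correlation none of the 8 passed (smallest 0.152), and edgeR called 0 genes, with 400 by unadjusted p and 7 by DESeq2. The knockout effect differed between basal-like and luminal-like cells in 3858 genes. Of 21 values tested for an outlying mouse 1 passed, the highest Kmt2d level of a control mouse (30.5 CPM, Dixon ratio 0.896), about as many as chance gives.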

How the results depend on the processing

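The settings named as added were chosen only after the results were seen, like the tests built on them; all others were planned. Replicate differences correlated at 0.355 to 0.753 among the 3 Kmt2 guide groups, at -0.103 to 0.0284 between these and sgControl and at 0.369 in the Cre system. Replicate numbers thus did not pair all groups, so the replicate block is given here only: it gave 1 gene in the Cre comparison, 0 for sgKmt2c, 10 for sgKmt2d, 17 with both guides and 9 between the single guides, and 6814, 5112 and 6802 genes in all, basal-like and luminal-like cells. Without the low-count filter the 5 bulk comparisons gave 34, 1, 26, 123 and 35 genes. DESeq2 gave 361, 23, 574, 616 and 467, with 2 for the interaction and 7 for the system difference. With each system alone every bulk comparison within a system gave 0, and the system difference could not be fitted. Leaving out 1 library gave 0 to 2 genes in the Cre comparison, 0 to 2 for sgKmt2c, and 0 to 3 between the single guides. Leaving out 1 mouse gave 6746 to 7458 genes in all cells, 5365 to 5620 in basal-like and 6445 to 7153 in luminal-like cells. For lists the value compared was the -log10 of camera's unadjusted p, negative where the list ranked lower. For interferon genes in sgKmt2c it was 3.67 with all libraries and -0.0872 to 9.54 without 1, and for luminal genes in the system difference 2.17 with all and -0.210 to 7.70 without 1, both reversed at the low end. Apart from these 2 reversals, list calls were lost in 9 cases and kept in 39 in the Cre comparison, 2 and 13 for sgKmt2c, 2 and 30 for sgKmt2d, 11 and 37 with both guides, 24 and 32 between the single guides and 31 and 56 for the system difference. In all, basal-like and luminal-like cells they were lost in 5, 12 and 12 and kept in 160, 204 and 159.

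In points of knockout minus control, the basal-like share was 10.2 at first and -8.05 without the changed genes, and the luminal-like share -10.2 and 8.01, both reversed. At resolution 1.0 the basal-like share was 1.41 (exact permutation p = 0.857), under projection 19.8 (0.0571) and with called doublets kept 16.9 (0.114). It was 44.9 with a threshold of 0, 21.4 with the margin of 1, 28.1 with margin and resolution 1.0, 19.9 with margin and projection, 27.5 with a minimum of 1000 UMIs, with or without the margin, and 22.8 with margin and without the changed genes. The luminal-like share in the same order was -44.8, -21.3, -27.7, -19.0, -28.2, and -22.8, each with an exact permutation p of 0.0286. With the margin and called doublets kept they were 16.9 and -16.9 (exact permutation p = 0.114 for each). The settings with a threshold, a margin or 1000 UMIs were added. With the threshold of 0 no control cluster was basal-like, so that rule fixed the control share at 0. Leaving out 1 mouse gave 6.28 to 13.7 points for basal-like and -14.1 to -5.86 for luminal-like cells. Of the class genes, Nrarp in basal-like cells had a log2 change of -3.26 at first and 0.00429 under projection. Wnt10a in luminal-like cells had one of 1.30 at first and -0.22 with the threshold of 0. Neither passed under the setting that turned its sign. Wnt10a also missed the threshold with 1000 UMIs (0.24) and under projection (0.25). The difference between classes held 3858 genes, and 4359 with the margin, 4116 at resolution 1.0 and 3345 under projection. Of the 3858, 2756, 3272 and 2087 passed there in the same direction and 26, 2 and 27 in the opposite one. The correlation of Cre and double-guide changes was 0.594 for genes of at least 10 CPM, 0.258 with DESeq2 and 0.452 to 0.512 without 1 library (0.467 without double-guide library 1, 0.453 and 0.476 without Cre knockout library 1 and 2). That of Cre and single-cell changes was 0.256 by rank, 0.268 for genes of at least 10 CPM, 0.247 with DESeq2 and 0.307 to 0.371 without 1 library or mouse. That of the classes was 0.806 by rank, 0.841, 0.740 and 0.868 to 0.877, and that of the single guides 0.167 to 0.607 without 1 library. The cause of these moves was not tested.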

Other observations

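The mean of the 2 bulk double-loss effects, a test chosen only after the results were seen, used 8 libraries at once. Mkx rose by a mean log2 change of 3.33, the calcium channel subunit gene Cacna2d1 by 2.76, the zinc finger gene Zfp9 by 2.22, the KDEL receptor gene Kdelr3 by 2.21 and the syndecan gene Sdc2 by 1.60. Ngfr fell by 5.63, the sorbitol dehydrogenase gene Sord by 2.14, Ankrd22 by 1.25 and the ETS factor gene Etv5 by 1.18 (edgeR adjusted p between 0.0124 and 0.0176 for all of these). They were picked after their values were seen, and Cacna2d1 and Zfp9 lay under the log2 CPM minimum of 3 used elsewhere. The systems were unequal for some: Mkx changed by 5.196 in Cre organoids and 1.46 with both guides, and Sdc2 by 2.346 and 0.8541. Sord was more even, at -2.035 and -2.248. In all 364 genes passed, 197 higher and 167 lower, and 3178 had an unadjusted p under 0.05. Of those, 1686 also passed in the mice, and 72.2% of them, 1217 genes, changed in the same direction. In the mice 56.2% of all 13821 tested genes passed, so a large overlap comes with any set of genes.

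Among lists of this mean effect, the unfolded protein response (camera adjusted p = 4.48e-04), developmental transcription factors (0.00490), basal genes (0.00651), interferon genes (0.0105), immediate early genes (0.0108), squamous genes (0.0231) and Hox genes (0.0468) passed. With an estimated correlation the smallest adjusted p was 0.428. A mean can come from 1 system: camera adjusted p in the Cre and the double-guide comparison was 0.780 and 1.84e-10 for the unfolded protein response, 0.560 and 0.00119 for squamous genes, and 0.00173 and 0.618 for Hox genes. Of 18 regroupings of libraries within the systems, 1 of 18, the real one, gave 364 genes and the highest other 8. So few regroupings cannot give a share under 0.05.

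In the knockout mice, Mkx rose as well, by 4.96 on the log2 scale (edgeR adjusted p = 4.90e-06), and Cacna2d1 by 2.14, Kdelr3 by 2.44 and Sdc2 by 1.40, while Sord (-1.90), Ankrd22 (-2.72), Etv5 (-1.93) and Ngfr (-3.16) fell. Others did not follow: Esyt1 (0.72 in the mean effect, -0.33 in mice), Mamld1 (5.06 and -0.91) and Hk2 (-0.51 and 0.68) went opposite ways, and Kctd12, at 4.42, was at -0.04 in mice (edgeR adjusted p = 0.767). Of the 364 genes 304 were tested in mice, where 185 passed in the same direction, 35 in the opposite one and 84 did not pass.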
